A study of Homo sapiens with 18 samples.

How the data were processed

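Gene expression was measured on Illumina bead arrays carrying 48803 probes, with 1 array for each of 18 RNA samples of primary human CD4+ T cells. Each of 9 healthy donors gave a pair of samples, cells treated with suberoylanilide hydroxamic acid (SAHA) at 340 nM for 24 h and control cells. Group, donor and batch were taken from the sample labels. The labels do not say what the control cells received. Batch 1 held pairs 1 to 3 and batch 2 held pairs 4 to 9. The arrays lay on 6 slides. Slide 1 held both arrays of pair 1, while every other pair had its arrays on different slides. Each slide held arrays of both groups, but not always evenly. Slide 4 held 3 SAHA arrays, those of pairs 7 to 9, and 1 control array, and slide 5 held 1 SAHA array and 3 control arrays. In batch 2 treatment was thus partly confounded with slide.

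Per the labels' protocols, total RNA was amplified in 1 round into biotin-labelled cRNA. Per the file headers, the deposited table that was analysed holds a mean bead signal for each probe and array, a raw fluorescence intensity on a linear scale with no normalization between arrays. Beside each intensity, the authors deposited a detection p-value, which ranks the probe among the negative control beads of its array. A value table of log2 size was also deposited by the authors, and the submitters' processing notes name lumi, without a version. The transform and normalization behind it are not given in the sources used here. Within an array its values ranked exactly as the signals did (lowest rank correlation 1), and over bright probes its slope against log2 signal ran from 0.88 to 1.06. Its column medians lay between 7.37 and 7.54. It held 17427 probes, the same ones that had a detection p-value under 0.01 on at least 1 array. This table served as an alternative, with the log base read from the slope and its centring unknown.

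Signals were background corrected and quantile normalized over all 18 arrays with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. The mean and spread of the negative controls were inferred from the detection p-values, since the table held no control probes. Probes with a detection p-value under 0.05 on at least 9 of 18 arrays were kept. Of all probes, 26251 were named through their transcript accession in a RefSeq gene table (assembly GRCh38.p14), 3020 through a current symbol or synonym and 6879 by the deposited symbol alone, and 12653 had no symbol. Spreadsheet software had turned 50 symbols into dates, and those probes were named through their accession where it was listed. XIST, Y-linked and pseudoautosomal probes (204) were left out. This left 13543 probes, of which 13040 had a gene name and 503 had none. For each gene the probe with the highest mean was taken, giving 10248 genes. Per array 12257 to 17365 probes were detected, and the number of arrays limits the precision.

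Each gene was fitted with limma (lmFit and eBayes) with donor as a block and treatment as the tested term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Folds of at least 1.5 were counted among the called genes. Standard errors (SE) are those of this fit over 9 pairs. Donors are separate people, and the p-values measure how the SAHA-minus-control difference varied between them. That spread also holds differences between slides, since most pairs had their arrays on different slides. The pairing came from the donor named in each label. The deviations of a donor's arrays from their group means correlated at 0.40 to 0.83, and at 0.11 to 0.60 after batch means were removed, while arrays of different donors of one batch reached at most 0.13. With no block of any kind 676 genes were called, and with batch as a covariate in place of donor 1517. Part of that loss thus came from leaving out batch. No arrays held identical values. An interaction term tested whether the response differed between batches, and each batch was also fitted alone.

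Before the data were examined, 50 gene lists were fixed from general knowledge, covering chromatin regulators, cell cycle, T cell state, signalling, antiviral genes, stress, metabolism, protein synthesis and markers of other blood cells. Some were matched by symbol prefix. The 47 lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, in one direction, and does not compare them with other genes. The named genes were also set by rule at that time: the 10 largest rises and 10 largest falls among called genes with one sign in all 9 pairs, up to 4 members of each list with the smallest adjusted p, and 18 genes of prior interest, of which 15 were tested. A gene outside this rule is said to have been chosen after its values were seen.

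The steps were tested on simulated data made from the 10248 genes' own levels, donor differences and residual spread. The donor-block fit called 31.3% of 67 genes changed by 0.3 (log2), 73.1% of 67 changed by 0.6 and 98.5% of 66 changed by 1.0. Of its 139 calls, 4 (2.9%) were false. The data gave 2149 calls, and the adjusted threshold is stricter where fewer genes change. These shares thus do not give the sensitivity of the fit to the data. For a response differing between 3 and 6 pairs, the interaction term called 11.9% at 0.6, 37.3% at 1.0 and 84.8% at 1.5. A simulated list of 30 genes shifted by 0.3 was called, and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so false calls of lists with correlated genes were not tested. Alternatives covered the blocks (donor, slide, batch, donor as a random block), background correction, normalization, the detection filter, the probe chosen per gene, array weights, a trended and robust prior, a minimum fold of 1.2 in limma's treat, each batch alone and each pair left out. Values of single donors are not given for HLA, KIR and similar genes that differ between people. Figures were drawn with matplotlib 3.10.9.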

Results

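Suberoylanilide hydroxamic acid (SAHA, vorinostat) inhibits zinc-dependent histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. It is an approved drug for cutaneous T cell lymphoma and has been studied as an agent to reactivate latent HIV. The series asked which genes SAHA modulates in primary human CD4+ T cells, the helper cells of adaptive immunity. Cells of 9 healthy donors were exposed to 340 nM SAHA for 24 h and set against control cells of the same donors, giving 9 SAHA and 9 control arrays. An array detected 14392 ± 1913 probes with SAHA (SD, n = 9) and 14498 ± 1250 in controls (SD, n = 9). Detection differed more by batch, with 16357 ± 834 probes on the 6 arrays of batch 1 and 13490 ± 705 on the 12 arrays of batch 2 (SD).

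SAHA changed 2149 of 10248 genes (21%), with 1121 higher and 1028 lower. Most changes were small. The median fold among changed genes was 1.35, and 549 genes (348 higher and 201 lower) changed at least 1.5-fold. At least 2-fold changes were found for 113 genes (83 higher and 30 lower), at least 3-fold changes for 14 genes, and the fitted change of TCN1 alone exceeded 4-fold. Among the changed genes, 1222 moved one way in all 9 pairs. Of all tested genes 1302 did so, where chance alone gives 0.39%. The balance of rises and falls depended on the scaling: with arrays centred on their median in place of quantile normalization, the median gene shifted by -0.157 (log2), and 483 genes were higher and 1286 lower (27.3% higher against 52.2%). At 1.5-fold that scaling gave 242 higher and 405 lower (37.4% higher against 63.4%), and without background correction 116 were higher and 35 lower (76.8%). Of the 2149 genes, 2 had the opposite sign after median centring, and neither was called there.

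**Figure D1:**
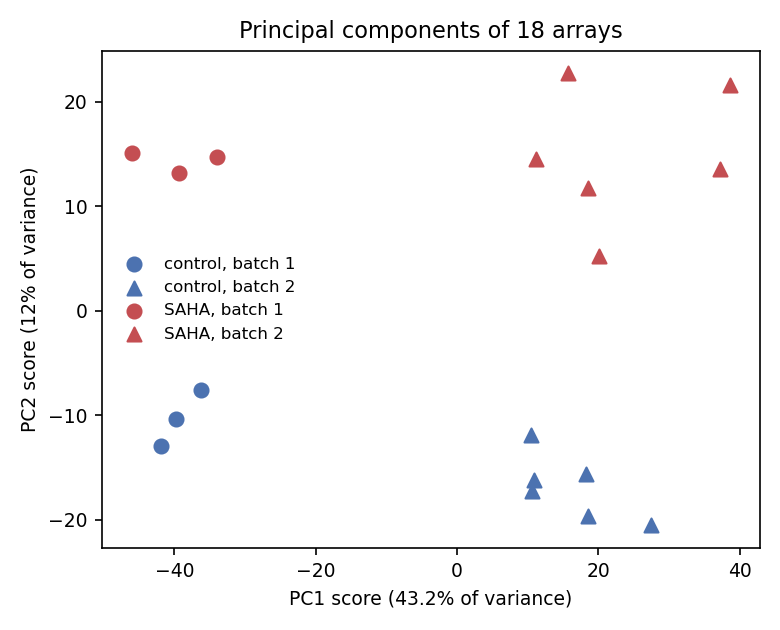
Principal component scores of the 18 arrays over the tested genes, without units. Colour gives the group and marker shape the batch. The first component (43.2% of variance) parts the batches, and the second (12%) parts SAHA arrays (5.22 to 22.72) from control arrays (-20.54 to -7.55).

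The response was measured in both batches. In batch 1, 473 genes were higher and 335 lower with SAHA over 3 pairs. Batch 2 had 619 higher and 433 lower over 6 pairs. Both batches called 479 genes, every one in a single direction: 312 higher, where independent lists would share 28.6, and 167 lower, where they would share 14.2. Across genes, which are not independent replicates, the fold changes of the batches correlated at r = 0.69 (rho = 0.585). No gene passed the limma interaction test for a response that differed between batches (0 genes, smallest adjusted p = 0.997), and 441 genes (4.3%) had an unadjusted p under 0.05. At this number of pairs the simulated test found few differences below 1.0 on the log2 scale. Slides gave a finer grouping. With donor and slide both as blocks 1601 genes were called, 1505 of them among the 2149. With no block at all 676 were called, with slide alone as the block 1137 and with batch alone as a covariate 1517.

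**Figure D2:**
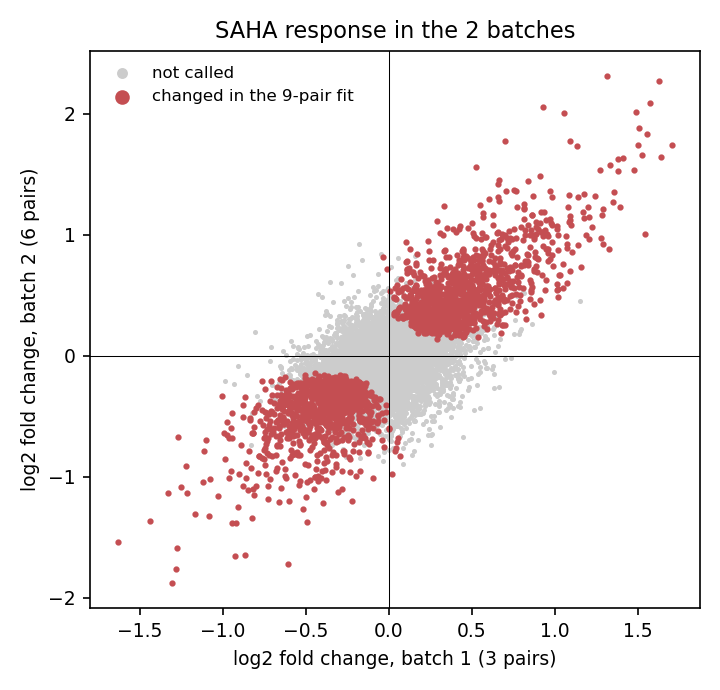
Log2 fold change of SAHA over control in batch 1 (3 pairs, x axis) against batch 2 (6 pairs, y axis) for 10248 genes, 1 point per gene. The 2149 genes changed over all 9 pairs are in red and lie mainly in the quadrants where both batches share a sign. Calling them over both batches favours this by itself. Across all genes r = 0.69.

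The strongest rises and falls were found in genes of varied function. TCN1, which encodes the vitamin B12 binding protein haptocorrin, was 4.16-fold higher (log2 fold change 2.06 ± 0.29, SE, adjusted p = 0.000456), with a wide spread between pairs (SD 1.06). It was detected on 5 of 9 control arrays and was at least 3.76-fold higher, with undetected arrays at the lowest detected signal of their array. FLJ42957, a transcript without a settled function, was detected on 1 of 9 control arrays and 9 of 9 SAHA arrays and was at least 3.05-fold higher by the same bound. HLA-DMB, part of the complex that loads peptides onto MHC class II molecules, was 3.77-fold higher (1.91 ± 0.14, adjusted p = 4.02e-06). COL9A2, a chain of type IX collagen detected on 5 control arrays, was at least 3.28-fold higher, the zinc finger gene ZNF467 rose 3.38-fold, and CACNB3, a subunit of voltage-gated calcium channels, rose 3.34-fold. EXTL2, a glycosyltransferase of heparan sulfate synthesis, rose 3.32-fold, SEPTIN4 3.21-fold and RIMS3, known from synaptic vesicle release, 3.16-fold. NRM, which encodes the nuclear membrane protein nurim and was detected on 4 control arrays, was at least 2.79-fold higher. These 10 genes were higher in all 9 pairs, which the rule that chose them required. A second detected probe of SEPTIN4 had the same sign but was not called. The lowest folds given as bounds, here and below, hold for the main normalization only. In the authors' value table the log2 change of TCN1 was 1.62, below its bound of 1.91 on that scale.

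Among the falls, C16orf74 fell by 1.69 ± 0.14 on the log2 scale (adjusted p = 1.06e-05), ACYP2, an acylphosphatase, by 1.60 ± 0.15 and CDH23, a cadherin of inner ear hair cells, by 1.57 ± 0.11. GTF2IRD2B fell by 1.39, and GTF2IRD2P1 and GTF2IRD2, detected on 5 and 4 of 9 SAHA arrays, were at least 2.48-fold and 2.02-fold lower. They are near-identical copies, and their probes may share targets, so they count as 1 observation. AGMAT, an agmatinase, fell by 1.26. APOBR, a receptor for apolipoprotein B48, was detected on 5 SAHA arrays and was at least 2.34-fold lower. HKDC1, a hexokinase family member, was detected on 4 SAHA arrays and was at least 2.04-fold lower. PMF1, a kinetochore protein, was detected on 3 SAHA arrays and was at least 1.84-fold lower, and batch 1 alone did not call it (adjusted p = 0.0576). All 10 were lower in each of the 9 pairs, as the rule required.

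**Figure D3:**
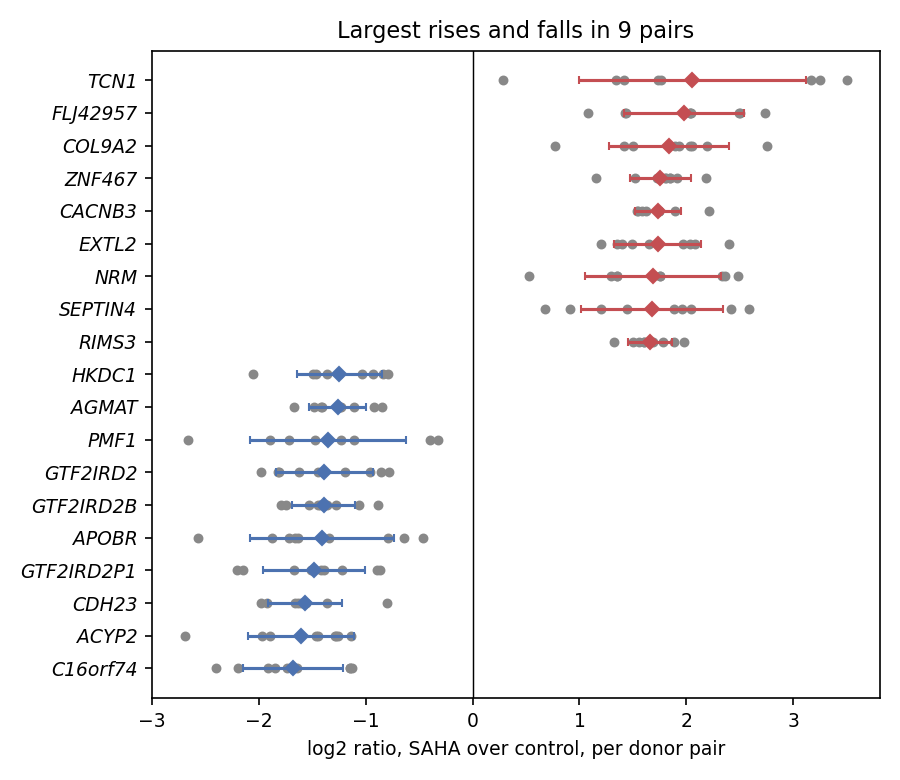
Log2 ratio of SAHA over control (x axis) for the genes with the largest rises and falls among those of one sign in all 9 pairs, leaving out HLA-DMB. Grey points are donor pairs, diamonds the mean and bars the SD of the 9 pairs. Where an array did not detect a gene, its point rests on a background value. TCN1 has the widest spread (SD 1.06), and every pair of each gene lies on one side of 0 by the choice of genes.

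Histone genes rose as a group. Of 21 measured, 10 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median log2 change of 0.26 (camera adjusted p = 2.35e-05, and adjusted p = 0.0539 with an estimated correlation). The linker histone genes H1-2 and H1-10 rose by 1.09 and 0.95 and the variant H2AJ by 0.88, all in 9 of 9 pairs. Some histone probes match near-identical copies, so single members are less certain than the group.

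Of 13 HDAC and sirtuin genes, SIRT4 rose by 0.48 and SIRT1 and SIRT7 fell by 0.28 and 0.38 (camera adjusted p = 0.949 for the list). The calls of SIRT1 and SIRT7 were each kept in 11 of 27 alternative settings. HDAC1, HDAC2 and HDAC3, the class I targets of SAHA, had log2 changes of 0.13, 0.22 and 0.15 and were not called (adjusted p = 0.263, 0.229 and 0.239). HDAC2 was called with array weights (adjusted p = 0.0497) and in the 5 pairs with no array on slide 4, a choice made after seeing the data. Of 27 acetyltransferase and bromodomain genes 0 were higher and 6 lower (camera adjusted p = 0.158). They included the scaffold BRPF3, which fell by 0.95, the acetyltransferase CREBBP (by 0.29) and BRD1 (by 0.29). The acetyltransferase KAT6B, detected on 5 SAHA arrays, was at least 1.34-fold lower. In the corepressor complexes that carry HDACs, 8 of 32 genes were higher and 2 lower (adjusted p = 0.11), with rises of ING2 (0.64), SAP30 (0.63), PHF21A (0.39) and HMG20B (0.29). Among 28 genes of polycomb and of histone and DNA methylation, 5 were higher and 3 lower (adjusted p = 0.976). EZH2, the methyltransferase of polycomb complex 2, and CBX3 rose by 0.69 and 0.35, while DNMT1, the maintenance DNA methyltransferase, and PHC3 fell by 0.37 and 0.38. A second detected probe of CBX3 had the opposite sign. KDM2B was the 1 gene called among 12 histone demethylases (-0.30, adjusted p = 0.641 for the list).

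Metallothionein genes, which encode small metal-binding proteins, were higher for 4 of 6 members (4 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00446, and adjusted p = 0.191 with an estimated correlation). MT2A rose 2.14-fold, MT1A by 0.65, MT1X by 0.39 and MT1F by 0.32, although probes for these close relatives may read each other's transcripts. Glycolytic and hypoxia-responsive genes rose for 9 of 31 members and fell for 1 (12 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.00355, and adjusted p = 0.166 with an estimated correlation). The phosphofructokinase genes PFKM and PFKP rose by 0.95 and 0.56, the phosphofructokinase regulator PFKFB4 by 0.89 and GAPDH by 0.55. Autophagy and lysosome genes were higher for 11 and lower for 2 of 50 (14 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.0253, and adjusted p = 0.214 with an estimated correlation). They included GABARAPL1, a protein of autophagosome membranes, with a rise of 1.01, the proton pump subunit ATP6V0A1 (0.73), the lysosomal peptidase TPP1 (0.42) and the protease ATG4A (0.42). This call ended with donor and slide as blocks (adjusted p = 0.0836), after median centring (0.129), in batch 1 alone (0.38), with array weights (0.0513), in the 5 pairs with no array on slide 4 (0.201, chosen after seeing the data), and without pair 7 (0.0623) or pair 8 (0.0623). Tubulin, kinesin and microtubule genes were higher for 11 and lower for 2 of 34 (12 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.0478, and adjusted p = 0.182 with an estimated correlation). The kinesin KIF5C rose by 0.90, the microtubule-destabilizing STMN1 by 0.88, and the plus-end binding MAPRE3 and MAPRE2 by 0.74 and 0.47. Donor and slide blocks ended this call too (adjusted p = 0.0762), as did batch 1 alone (0.0579), batch 2 alone (0.0931), array weights (0.0513), the 5 pairs (0.0839) and leaving out any of pairs 3, 7 and 8 (up to 0.0716). After median centring, the median change of the glycolysis, autophagy and microtubule lists was -0.02, -0.06 and -0.11, on a scale where the median gene lay at -0.157.

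Nucleolar and ribosome biogenesis genes fell. Of 38 measured, 0 were higher and 10 lower (13 lower adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00355, and adjusted p = 0.054 with an estimated correlation). BOP1 and RRP12, which act in rRNA processing, fell by 0.67 and 0.57, and POLR1C, a subunit of RNA polymerases I and III, by 0.43. The nucleolar protein MYBBP1A, detected on 4 SAHA arrays, was lower by at least 0.26 on the log2 scale. MYC, a transcription factor that drives such genes, fell by 0.60 ± 0.12 (adjusted p = 0.00414, lower in 8 of 9 pairs), and in batch 2 alone it was not called (-0.60, adjusted p = 0.0535). Batch 1 alone, with 3 pairs, did not call the list (adjusted p = 0.0647).

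**Figure D4:**
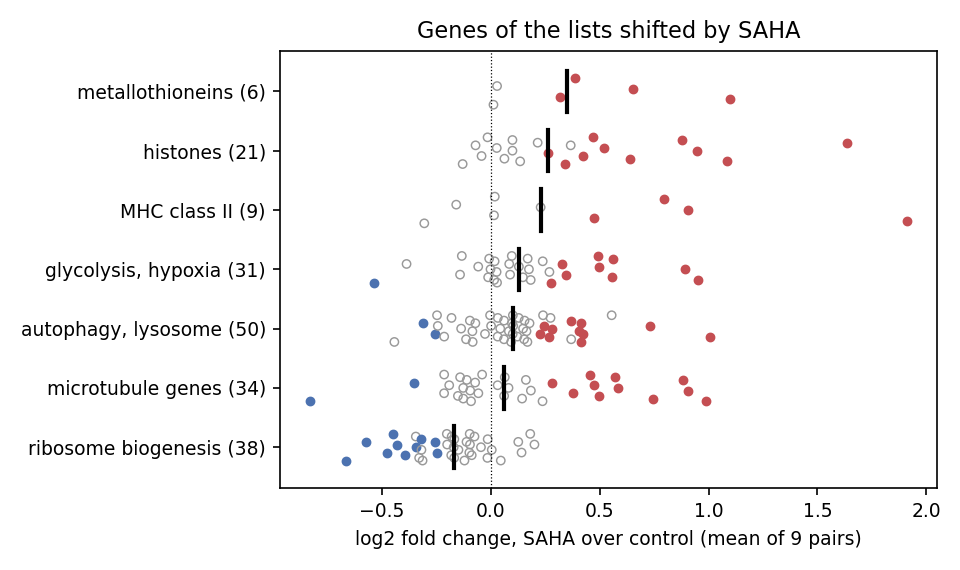
Log2 fold change of SAHA over control (x axis, mean of 9 pairs) for each measured member of the 7 lists called by camera at the preset correlation. Filled points passed the test for single genes, open points did not, and black bars are medians, from 0.35 for metallothioneins to -0.17 for ribosome biogenesis.

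Genes of MHC class II presentation were higher for 4 of 9 members and lower for 0 (4 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.0253, and adjusted p = 0.205 with an estimated correlation). HLA-DMB rose as above, HLA-DMA by 0.91, the invariant chain CD74 by 0.80 and HLA-DPA1 by 0.48, each in 9 of 9 pairs. HLA probes can respond to allele differences between donors, which cancel within a pair only in part. Markers of other cells moved as follows beside this group. Of 4 B cell markers CD79A and CD79B fell by 0.49 and 0.36, CR2 rose by 0.48, and MS4A1 was not called (-0.23). Of 7 monocyte markers FCER1G and CD14 fell by 0.56 and 0.40, AIF1 rose by 0.50, and TYROBP was not called (-0.50, camera adjusted p = 0.284 for the list). Among 6 NK and CD8 T cell markers GNLY fell by 0.45 (adjusted p = 0.194 for the list). None of 3 platelet and red cell markers was called (HBD -0.31, HBA2 0.14 and HBB 0.09), nor was the dendritic cell marker FCER1A (0.23). The B cell, platelet and dendritic lists were too small for the list test. On slide 6, with 2 arrays of each group, the median of the MHC class II list was lower with SAHA (-0.331). The SAHA and control arrays of that slide came from different donors, so this contrast was not paired. Without the 4 pairs that had an array on slide 4, a choice made after seeing the data, the list was not called (camera adjusted p = 0.0628).

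Genes of T cell state went both ways. Of 21 activation genes 4 were higher and 1 lower (camera adjusted p = 0.165), with rises of the AP-1 component JUN (0.90), the early activation antigen CD69 (0.76 ± 0.13, adjusted p = 0.00116) and HAVCR2, which encodes TIM-3 (0.48). CD69 was not called without the donor block (adjusted p = 0.0974). Effector and memory genes were higher for 6 and lower for 6 of 29 (adjusted p = 0.854), led by LGALS1, which encodes galectin-1, with a 3.05-fold rise, and with rises of ANXA1 (0.58), the chemokine receptor CCR2 (0.61) and ANXA2 (0.37). BCL6, the transcription factor of follicular helper cells, rose 2.32-fold and CXCR5, a receptor of the same cells, by 0.35, though a second detected probe of CXCR5 had the opposite sign. IL12RB1 and SMAD7 fell by 0.61 and 0.50, and over 28 T helper genes 4 were higher and 4 lower (adjusted p = 0.79). Cytokine and receptor genes were higher for 5 and lower for 3 of 34 (adjusted p = 0.854), and IL27RA and LTB fell by 0.73 and 0.39. T cell receptor signalling genes were lower for 5 of 42 and higher for 1 (adjusted p = 0.976). The phosphatases PTPN6 and UBASH3A and the paracaspase MALT1 fell by 0.41, 0.40 and 0.48, and CD2 rose by 0.31. Naive and quiescence genes were lower for 2 of 29, MYC among them, and higher for 0 (adjusted p = 0.409). RUNX1 and FOXO1 of that list were not called (-0.19 and -0.18). Of 31 adhesion and migration genes 1 was higher and 4 lower (adjusted p = 0.055), among them CORO1A (-0.46), S1PR4 (-0.73) and CDC42SE1 (-0.43), while CD58 rose by 0.33. That list was called in 11 of 25 alternative settings (camera adjusted p from 0.0102 to 0.114).

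Genes of the cell cycle and of cell death showed single changes without a list call. Among G1 cyclins, CDKs and their inhibitors 5 were higher and 4 lower of 17 (camera adjusted p = 0.211). CDK2 rose 2.06-fold, CDK6 by 0.73, the inhibitor CDKN2C by 0.72 and CCND2 by 0.39, while a second detected probe of CDK2 was not called. CDKN1A, which encodes p21, had a log2 change of 0.49 ± 0.19, was higher in 8 of 9 pairs and was not called (adjusted p = 0.0867); without pair 4 it was called (0.65, adjusted p = 0.0107). Proliferation genes were higher for 1 of 17 (PTTG1, 0.64) and lower for 2 (GINS2 -0.67 and MCM5 -0.66, adjusted p = 0.409), and E2F2 was not called (-0.32). Of 20 p53 targets, GADD45A rose by 0.71 and AEN fell by 0.37 (adjusted p = 0.854), while DDB2 was not called (-0.48). Among 36 apoptosis genes 2 were higher and 4 lower (adjusted p = 0.877), including rises of TNFSF10 (0.31) and of BMF, which was detected on 1 of 9 control arrays and 9 of 9 SAHA arrays and was at least 1.43-fold higher, and falls of TNFRSF25 (-0.36) and RIPK1 (-0.47). DNA repair genes were higher for 6 and lower for 3 of 46 (adjusted p = 0.976), with FANCD2 lower (-0.77) and CHEK2 and RPA3 higher (0.53 and 0.43).

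Among factors that act at the HIV promoter and in antiviral defence, P-TEFb, 7SK and elongation genes were lower for 5 of 34 and higher for 0 (camera adjusted p = 0.379). MEPCE and LARP7, proteins of the 7SK particle that holds P-TEFb inactive, fell by 0.76 and 0.47 in 9 of 9 pairs, and LEO1 and NELFCD by 0.35 and 0.29. CDK9 and CCNT1, which form P-TEFb, had changes of 0.20 and -0.06, and HEXIM1 0.13, with no call (adjusted p = 0.112, 0.808 and 0.547). Of 35 factors described at the HIV-1 promoter 1 was higher, the architectural protein HMGA1 (0.88), and 4 were lower, with CREBBP and SMARCC1 (-0.24) among them (adjusted p = 0.877). NF-kappaB genes were higher for 6 and lower for 1 of 29 (adjusted p = 0.11). BCL3 rose 2.09-fold, TNFAIP3 by 0.47 and SOD2 by 0.26, and NFKBIZ fell by 0.40. Restriction factors were lower for 6 and higher for 3 of 27 (adjusted p = 0.213), with MX2 and MX1 lower in 9 of 9 pairs (-0.56 and -0.45), APOBEC3F lower (-0.51) and the nuclear envelope gene SUN2 lower (-0.42). Interferon-stimulated genes moved apart, with 8 higher and 7 lower of 45 (adjusted p = 0.779): GBP5 and IFIT1 rose by 0.54 and 0.50 while MX2, MX1 and HERC6 (-0.45) fell. Of 18 MHC class I genes TAP1 rose (0.30) and PSMB10 fell (-0.35), while HLA-E and CALR were not called (-0.30 and -0.16, adjusted p = 0.877 for the list).

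Neuronal genes were measured for 16 members, of which 7 were higher and 1 lower (camera adjusted p = 0.055). The synaptic adhesion gene NLGN2 rose by 1.23 on the log2 scale, STX1A and SYT11 of vesicle fusion by 0.96 and 0.90 and DPYSL2 by 0.66. MAP kinase feedback genes were higher for 6 of 28 and lower for 0 (adjusted p = 0.0601), with rises of SPRY1 (2.24-fold), DUSP10 (0.55) and MAPK3 (0.30). MAP3K8, detected on 4 control arrays, was at least 1.67-fold higher. Actin genes were higher for 4 and lower for 2 of 37 (adjusted p = 0.428), with CORO1B and CNN3 higher (1.11 and 0.72) and TPM2 lower (-0.67). Cholesterol and SREBP target genes were higher for 4 and lower for 3 of 28 (adjusted p = 0.456), with the desaturase FADS1, detected on 3 control arrays, at least 1.84-fold higher, the desaturase SCD higher by 0.95 and FASN by 0.25 on the log2 scale. Redox genes were higher for 6 and lower for 3 of 39 (adjusted p = 0.213), with TXN (0.52), GCLM (0.46) and GPX4 (0.30) higher and TXNRD2 lower (-0.56). Heat shock genes were higher for 3 and lower for 2 of 30 (adjusted p = 0.739). HSPA1B and HSPA1A, near-identical copies, rose by 0.64 and 0.36, and HSPA1L and DNAJB1 fell by 0.79 and 0.30. In the stress response list 2 of 30 were higher and 2 lower (adjusted p = 0.927), the former TRIB3 (0.60) and DDIT4 (0.53), the latter ATF5 (-1.02) and the amino acid transporter SLC7A5 (-0.77).

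Genes of the basic machinery were mostly uncalled. Of 99 genes with a ribosomal protein prefix 5 were higher and 1 lower (camera adjusted p = 0.877). This prefix also took in 8 kinase genes of the RPS6K family, of which RPS6KA2 and RPS6KA3 rose by 0.86 and 0.36, and RPS21 fell by 0.43 while RPL37 rose by 0.42. Second detected probes of RPS6KA3 and RPL37 had the opposite sign. Mitochondrial ribosomal genes were lower for 6 of 77 and higher for 0 (adjusted p = 0.0588), led by MRPL54 (-0.95), MRPL27 (-0.50), MRPL11 (-0.31) and MRPL22 (-0.28). Oxidative phosphorylation genes were called for 3 of 66 (adjusted p = 0.927), with ATP5F1D at 0.51, where a second probe had the opposite sign, SDHC at -0.36 and NDUFS1 at -0.32. Proteasome genes had 1 rise (PSMA5, 0.20) and 1 fall (PSMB10) among 37 (adjusted p = 0.927), calls kept in 6 and 12 of 27 alternative settings. Translation factors were lower for 3 of 37, EIF3B (-0.34), EIF2B1 (-0.31) and EIF4A1 (-0.26), and higher for 0 (adjusted p = 0.854). Splicing factors were lower for 4 of 49, SRSF7 (-0.57), SRSF6 (-0.32), HNRNPC (-0.26) and HNRNPR (-0.25), and higher for 0 (adjusted p = 0.156). Of 293 genes with the ZNF prefix 27 were higher and 29 lower (adjusted p = 0.877), with ZNF580, ZNF821 and ZNF581 higher by 1.03, 0.97 and 0.68. Of 15 reference genes GAPDH and HPRT1 (0.36) rose, and ACTB was not called (-0.17, adjusted p = 0.927 for the list). For 12 of the 47 tested lists the median, the mean and the camera direction did not share a sign, and none of these was called. Other calls kept in under 14 of 27 alternative settings were those of NDUFS1 (9), EIF4A1 (10), SMARCC1 (12), TNFSF10 (12), AEN (13) and SOD2 (13). Further detected probes of MRPL27, CDC42SE1, UBASH3A, TNFRSF25, CD79B, NELFCD, MRPL22, HNRNPC, GPX4, ANXA2, GCLM, TXN, CHEK2 and STMN1 had the sign given here and were not called.

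Among the genes of prior interest, CD69 and MYC were called, as given above. BCL2 (-0.18, adjusted p = 0.116), NFKBIA (0.01, adjusted p = 0.949), CXCR4 (-0.07, adjusted p = 0.566), CD4 (0.03, adjusted p = 0.885) and IL2RA (0.14, adjusted p = 0.524) were not. BCL2 was called after median centring (adjusted p = 0.0307), and CDK9 in the authors' value table (adjusted p = 0.0485). TYMS was not tested, as its probe was detected on 1 of 18 arrays.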

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

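Tests of the slopes in pairs with an array on slide 4 and of cell markers beside the MHC class II genes were chosen only after the result was seen. For the other explanations weighed here, tests were set before their values were known. No such record exists for the swaps of detection counts or for the count of splits at an unadjusted p. Among the named genes 209 were examined for 1 pair standing far from the other 8, measured by the gap to the nearest pair over the whole range. This holds for 9 of them, and chance gives about 10.5. The log2 ratio of the distant pair was 0.1777 for ACTB (others -0.34610 to -0.09016), 1.60 for BCL6 (others 1.031 to 1.289), -0.688 for CD79B (others -0.428 to -0.1694), 0.1601 for FOXO1, 1.508 for HSPA1B, 0.2515 for RPS6KA2 (others 0.7835 to 1.114), 0.9974 for RPS6KA3, -0.5125 for RUNX1 and -0.2905 for TNFAIP3 (others 0.4306 to 0.7294). Of 46 lists, the proteasome genes had 1 distant pair, at a median of 0.1038, and chance gives 2.3. Among array measures the control array of pair 4 had a median signal of 179.9 where the other control arrays had 85.6 to 133, and it lay on slide 4.

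In the 4 pairs with an array on slide 4, ratios of SAHA to control spread more widely. Over genes not called (adjusted p above 0.5), their spread relative to pairs 5 and 6 of the same batch was 1.278 on average in the dimmest genes and 1.371 in the brightest. A higher background of slide 4 should widen dim genes more, which held in 1 of the 4 pairs, and it cannot be told apart for the dim genes, whose spread was raised too. A larger response to SAHA in these donors cannot be told apart either: their slopes on the change in the other pairs ran from 0.729 to 1.008 (mean 0.910), against 0.862 and 1.011 for pairs 5 and 6. An effect of slide 4 itself could account for the spread: pair 4, with its control on that slide, had ratios that ran against the mean of pairs 7 to 9, with SAHA there (correlation -0.456 over 3897 uncalled genes, against -0.257 and -0.246 for pairs 5 and 6, where choosing uncalled genes alone gives negative values). Pairs 7 to 9 had correlations of -0.076 to 0.090 with each other. Choosing uncalled genes lowers these values too, so they cannot decide whether the 3 pairs share an effect. A slide effect common to them remains a hypothesis.

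MHC class II genes rose, while markers of other cells moved both ways. The 11 measured markers of B cells and monocytes did not rise with them. Their median log2 change was -0.291 against 0.229 for the class II list, and lower in 9 of 9 pairs (exact sign test, two-sided p = 0.00391). More of these cells in the SAHA cultures cannot be judged from this. SAHA may change marker transcripts themselves, and the class II list was set beside them because it rose. Of these markers 2 were higher (CR2 and AIF1) and 4 lower. More dendritic cells cannot be told apart, since 1 marker was measured, FCER1A, with a change of 0.231 that was not called. An action of SAHA on the T cells stays open as a hypothesis and was not tested.

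Probes outside the comparison also carried signal. Of 503 tested probes without a current gene name, 46 were higher and 31 lower with SAHA (15.3%, against 18.2% of named probes). Among probes too dim to be tested, those of 31 genes were detected on at least 6 SAHA arrays and at most 1 control array, and those of 19 genes the other way round. Some of these genes may have been tested through another probe. In 99 swaps of SAHA and control within pairs the larger of these counts reached at most 26. CORO6, chosen after its values were seen, was detected on 8 SAHA arrays and 0 control arrays and was at least 2.78-fold higher, taking the lowest detected signal of each control array as its bound there. MEX3B, TRIP10 and PPP4R4, chosen likewise and detected on 0 control arrays, were at least 1.59-fold, 1.44-fold and 1.44-fold higher. These genes had the largest bounds among those detected on 0 arrays of a group. For the rest, in either direction, the bounds ran from 0.97 (BAIAP2L1) to 1.19 (KLHDC9), and a bound near or below 1 shows no change.

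Chance was weighed by refitting the data with SAHA and control swapped within pairs, the real split and 99 others drawn from 256. The real split called 2149 genes, more than any other (1 of 100, highest other 513, with 1 pair swapped), and 549 genes at 1.5-fold (1 of 100, highest other 216), so chance can be excluded for both. It called 7 lists, and 2 of 100 splits, the real one among them, called as many (highest other 7). Few splits reached the real count at the preset correlation, but another tied it and an estimated correlation gave 0 lists. Chance is thus not excluded for the lists. For the response by batch the real count was 0 genes, which all 84 splits of the 9 pairs into 3 and 6 reach by construction (84 of 84, highest other 8). At an unadjusted p under 0.05, 43 of the 84 splits gave at least the real count of 441 genes, so chance cannot be excluded.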

How the results depend on the processing

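Only the restriction to 5 pairs was chosen after seeing the data. Over the settings tried, the genes changed by SAHA ranged from 676 to 2414, and at every probe 2451 probes were called. The count was lower with no block at all (676) and with slide as the block in place of donor (1137). It was also lower in batch 1 (808) and batch 2 (1052) alone and in the 5 pairs with no array on slide 4 (1427). Fewer samples entered these last 3 fits. Genes changed at least 1.5-fold numbered 205 with normexp at an offset of 50, 151 without background correction, 319 in the authors' value table and 320 among genes detected on all 18 arrays, against 549. A larger offset or no subtraction shrinks folds by construction, and the last tested 7635 genes. List calls numbered 12 after median centring, 16 of 50 lists tested with no filter, 0 with an estimated correlation and 26 by fry, against 7 of 47. Fry does not compare a list with other genes, so its count answers another question. The cause of the other differences was not tested. Leaving out each pair gave 1754 to 2015 changed genes, 530 to 597 at 1.5-fold and 5 to 9 lists. No alternative called a gene for a batch difference (0 genes in each). Of the 2149 genes 1505 were also called with donor and slide blocks and 1996 in the authors' table, all with the same sign. Median centring called 1769 genes, 1436 of them shared. Of 178 called named genes 68 kept their call in every setting, and 1 result reversed: CBX3, at -0.008 with the mean of its probes. The histone, glycolysis and metallothionein lists were called in every camera setting at the preset correlation that tested them, with adjusted p up to 0.000415, 0.0305 and 0.0163. Lists were not tested with donor as a random block or at every probe, nor metallothioneins among genes detected on all 18 arrays. Signal over background limited which genes could be tested.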

Other observations

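Tests of the detection floor and of a gap made by the change itself were chosen only after the result was seen. RIMS3 and CACNB3, both known from neurons and in none of the fixed lists, had the smallest adjusted p of all tested genes (3.44e-07 each in the limma fit, higher in 9 of 9 pairs). Their ratios varied little between pairs (SD 0.20 and 0.21). RIMS3 was higher by 1.503 in batch 1 and 1.74 in batch 2 on the log2 scale, and CACNB3 by 1.56 and 1.83.

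Genes higher with SAHA had lower control levels than genes lower with SAHA (median log2 level 7.66 against 8.31, and 7.95 over all tested genes). Regression to the mean of the same control arrays is argued against: with genes called in one batch and levels read from each control array of the other, the gap lay between -0.959 and -0.605. A detection floor that leaves dim genes no room to fall cannot be told apart. With genes sorted by their mean level over both groups in the other batch, the share of rises among called genes fell from genes of middle level to the brightest by 8.2 percentage points for genes called in batch 1 and by 16.7 for genes called in batch 2, and the former lay within 2 standard errors. Earlier tests, a gap within the brighter genes and an order by control level, were set aside because the way genes were sorted forces their outcome. A gap made by the change itself, with raised and lowered genes sharing one mean level, stays open too: the gap in mean level was -0.294 for genes called in batch 1 and -0.039 for genes called in batch 2.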
